A study of Mus musculus with 18 samples.

How the data were processed

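Cortex was dissected from 7-month-old C57BL/6 mice, either wild type at Mecp2 (WT) or heterozygous for a mutant Mecp2 allele (MUT), which had been fed a diet with 0.1, 1 or 10 IU of vitamin D per g from 4 weeks of age. The 2 genotypes and 3 diets gave 6 groups of 3 libraries, 18 in all. Libraries were made from total RNA with a QuantSeq 3' kit, per the labels' protocols; this chemistry keeps strand and reads a tag near the 3' end of each polyadenylated transcript, so 1 tag stands for 1 transcript whatever its length. Reads were aligned with STAR 2.7.3a to the mouse genome mm10, per the submitters' processing notes. The counting tool and its settings are not given in the sources used here. The labels number the replicates and do not state a batch, a litter or a day. They do not say in so many words that each library is a separate animal. P-values and SDs therefore measure the spread between these libraries that is left in the normalized values after unwanted variation was removed, as described below.

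The series table of raw counts had 18 columns under codes that match no label, so none was tied to a sample and that table was not used. The deposited normalized table, whose columns carry the sample titles, held 18018 genes as whole numbers, and its unit is treated as a score: the authors rounded counts after removing unwanted variation with RUVr, a method that estimates hidden factors from the residuals of a first fit and regresses them out, per the file's name. The number of factors and the first fit are not given in the sources used here. No gene had a highest value below 10, so genes of low level had been left out. Totals of these values ran from 19805887 to 21357393 per library; they follow the normalization and are not sequencing depth, which is unknown here. No interval or detection floor that needs depth is given. No pair of libraries had equal values at more than 4.23% of genes, so no library was counted as a duplicate.

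The planned test, the quasi-likelihood test of edgeR on raw counts, was not used because the count columns could not be tied to samples. Values were tested instead with limma 3.58.1 (trend and robust options, R 4.3.3) on log2(value + 1), in 1 model with 6 group means fitted to all 18 libraries. Fold changes are on that scale, which understates the change of genes at low values. Within groups the table had 9 directions of variation with singular values of 20.22 to 56.96 and 3 nearly empty ones (3.761, 3.397 and 2.833). Those 3 directions entered the model as covariates, which left 9 residual degrees of freedom in place of 12. This choice departs from the design fixed before the data were examined; the 3 directions were found before any gene was tested, but the numbers of genes called at 1 IU/g with 9 and with 12 degrees of freedom (61 and 956) had both been seen when the choice was settled. The simulations below were run after it. Results with 12 degrees of freedom are given as an alternative. P-values were adjusted by Benjamini-Hochberg over 18018 genes in each contrast, and genes were called at an adjusted p under 0.05 with no fold minimum. In the text, a p beside a gene is the limma adjusted p. Values per group are mean ± SD with n = 3, and SE is the standard error of the log2 fold change.

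In all, 14 contrasts were tested: MUT against WT within each diet and averaged over the diets, each diet against 1 IU/g within each genotype and averaged over genotypes, 10 against 0.1 IU/g within each genotype, and the differences of the genotype effect between 10 and 1 and between 0.1 and 1 IU/g. Before the data were examined, 31 lists of pathway genes and of markers of cell types and brain regions were fixed, all with at least 5 measured members. They were tested with camera from limma at a preset correlation between genes of 0.01, 2-sided, adjusted over the 31 lists of a contrast, and again with the correlation estimated from the data. Fry from limma tested whether the genes of a list moved 1 way on balance. Members were counted over all genes tested and adjusted over the list alone.

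The rule for genes named in the text, fixed before the data were examined, took Mecp2, Xist and Y-linked genes as a check of labels, up to 12 higher and 12 lower genes with the smallest p in a contrast (6 and 6 for the differences), members of each list that passed, or otherwise its members with the smallest p, and a few genes of vitamin D and NF-kB biology as values. Symbols of predicted or clone genes were counted and not named. It was carried out with 12 and 12 genes taken, of which the text names a part, for MUT against WT at 1 IU/g and averaged over diets, and with 4 and 4 elsewhere. Members were named for lists that passed, and for the lists of reported responders to MeCP2 loss and of vitamin D genes. Nuclear transcripts, Klk6 and genes called in each diet were chosen after their values were seen.

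Gene positions, lengths and biotypes came from GENCODE mouse release 21 on mm10, matched by symbol for 17653 genes (98.0%). Base composition was taken over the last 100 bases of transcripts, and over bases 800 to 1200 from the end as a control, for 97.8% of genes. The leading axis of the libraries was the first principal component of log2 values centred per gene, over 13023 genes with a mean above 50.

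The limma steps were tested on simulated data for MUT against WT, 3 against 3 libraries and 18018 genes with 200 changed genes, in 5 simulations. With independent noise and 9 degrees of freedom, 40.3% of genes changed by a log2 fold of 0.5 were recovered, 71.6% at 1 and 93.3% at 2, and 6.3% of calls were false; with 12 degrees of freedom 21.4% were false. Where the simulated noise held 3 shared factors that were then removed by the same route, 86.7% of calls were false at 9 degrees of freedom, and a contrast with no difference gave 2860 calls on average (0 to 8580). Removal of factors estimated from the libraries can therefore leave differences between groups that no test on this table can tell from an effect. In a simulation of independent noise with no factors removed and random lists of 25 genes, camera and fry each called 10 of 10 lists shifted by a log2 of 0.4. Both called 0 of 50 unchanged lists. Genes within these lists were not correlated, so this does not test false list calls where they are.

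Alternatives fixed before the data were examined and run here were a stricter filter on low values (at least 1 CPM in 9 libraries, applied to the normalized values, 15365 genes), the replicate number as a block, only the groups compared, an adjusted p under 0.10, 1 library left out at a time, other length thresholds, other p thresholds for choosing genes, and the list tests above. The TMM and RLE scalings, DESeq2, voom, no filter and RUVr factors on raw counts were not run, since they need the count columns. Added after the data were examined were 12 degrees of freedom for the lists, pseudocounts of 0.5 and 10, median scaling, array quality weights, removal of the trend on 3' base composition (lowess span 0.3), the leading axis as a covariate in a model with additive genotype and diet (for genes and for lists, these also with an estimated correlation), 1 diet left out, and the spread between diets or between genotypes as the error. The REML estimate of the array weights did not converge; its counts, which were larger, were seen and set aside, and the gene-by-gene estimate was used. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.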

Results

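Gene expression was measured in 18 libraries of mouse cortex in 6 groups of 3, which crossed 2 Mecp2 genotypes with 3 dietary levels of vitamin D. MeCP2 is an X-linked chromatin protein that binds methylated DNA, and its loss of function underlies Rett syndrome. A heterozygous female carries a mixture of cells that use the intact or the mutant allele. The control diet held 1 IU of vitamin D per g, and the others 0.1 and 10 IU/g. The design asks how the genotype changes the cortical transcriptome on each diet, how diet changes it in each genotype, and whether the genotype effect depends on diet. Values are the authors' normalized values, whose totals of 19805887 to 21357393 per library do not reflect depth, so depth is unknown.

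The widest difference between the libraries followed neither genotype nor dose in order. A single axis took 58.3% of the variance over 13023 genes, against 11.4% for the next, and 98.0% of its variance lay between groups. Both groups on 1 IU/g sat at 1 end, WT at 0.225 ± 0.0116 and MUT at 0.244 ± 0.0133 (SD, n = 3; root mean square log2 units). WT on 0.1 IU/g lay at the other end at -0.366 ± 0.0738, next to MUT on 10 IU/g at -0.25 ± 0.054, while MUT on 0.1 IU/g (0.106 ± 0.0193) and WT on 10 IU/g (0.0407 ± 0.0277) lay between. Across genes, fold changes correlated with the loadings on this axis at 0.87 for MUT against WT at 0.1 IU/g and at -0.82 at 10 IU/g, but at 0.08 at 1 IU/g. Genes are not independent replicates. Lists differed in where they sat on it: striatal markers had a median loading of 0.437 and oligodendrocyte and myelin markers 0.285, against -0.447 for choroid plexus and ependyma markers and -0.426 for endothelial markers.

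**Figure D1:**
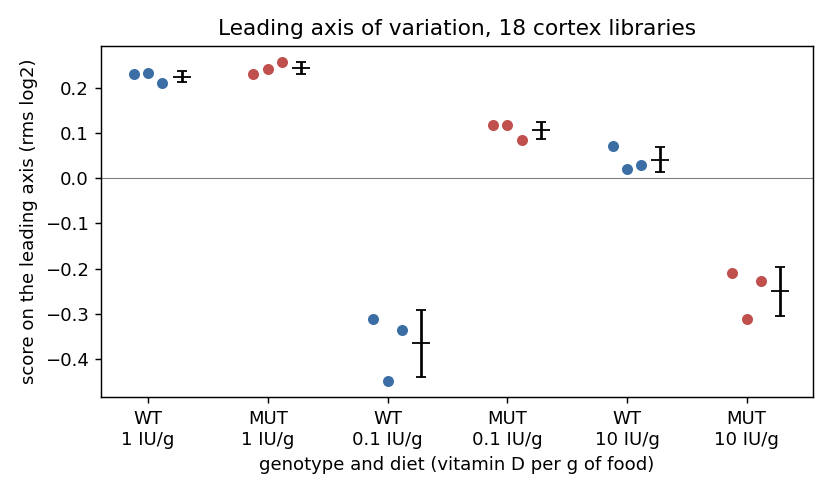
Score of each of the 18 libraries on the leading axis (root mean square log2 units) by diet and genotype, with points for libraries and bars for mean ± SD (n = 3). The groups on 1 IU/g sit together near 0.23, WT on 0.1 IU/g lies lowest at -0.366, and the order of WT and MUT on 0.1 IU/g (-0.366 and 0.106) is opposite to that on 10 IU/g (0.0407 and -0.25).

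Mecp2 itself was lower in MUT on each diet. On 1 IU/g it stood at 1823 ± 133 in WT and 1114 ± 226 in MUT, on 0.1 IU/g at 1741 ± 83.2 and 1043 ± 109, and on 10 IU/g at means of 1802 and 894 ± 165 (mean ± SD, n = 3). The 9 WT libraries ran from 1658 to 1965 and the 9 MUT libraries from 721 to 1360, so the genotypes did not overlap. The log2 difference was -0.73 at 1 IU/g (adjusted p = 0.059, short of the threshold), -0.74 at 0.1 IU/g (adjusted p = 0.0018), -1.02 at 10 IU/g (adjusted p = 0.00081) and -0.83 averaged over diets (adjusted p = 0.00018). Mecp2 (ENSMUSG00000031393.16) lies on the minus strand of chromosome X at 74026592 to 74135363 of mm10. The labels do not name the mutant allele, and a 3' tag may lie outside the deleted part, so these values check the labels only in part. The next gene downstream, Irak1 (ENSMUSG00000031392.18, X, 74013914 to 74023918, minus strand), a kinase of the interleukin-1 receptor pathway, was higher in MUT throughout. It stood at 578 ± 31.2 in WT and 832 ± 76.0 in MUT on 1 IU/g, at 630 ± 31.8 and 1020 ± 47.2 on 0.1 IU/g, and at 666 ± 9.87 and 1011 ± 120 on 10 IU/g. Its log2 difference was 0.69 at 0.1 IU/g (adjusted p = 6.5e-06), 0.59 at 10 IU/g (adjusted p = 0.00029) and 0.60 averaged over diets (adjusted p = 3e-06). Xist, the noncoding RNA of the inactive X, had values of 2644 to 5291 in the 18 libraries, and 0 of 4 Y-linked genes looked up were listed in the table.

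**Figure D2:**
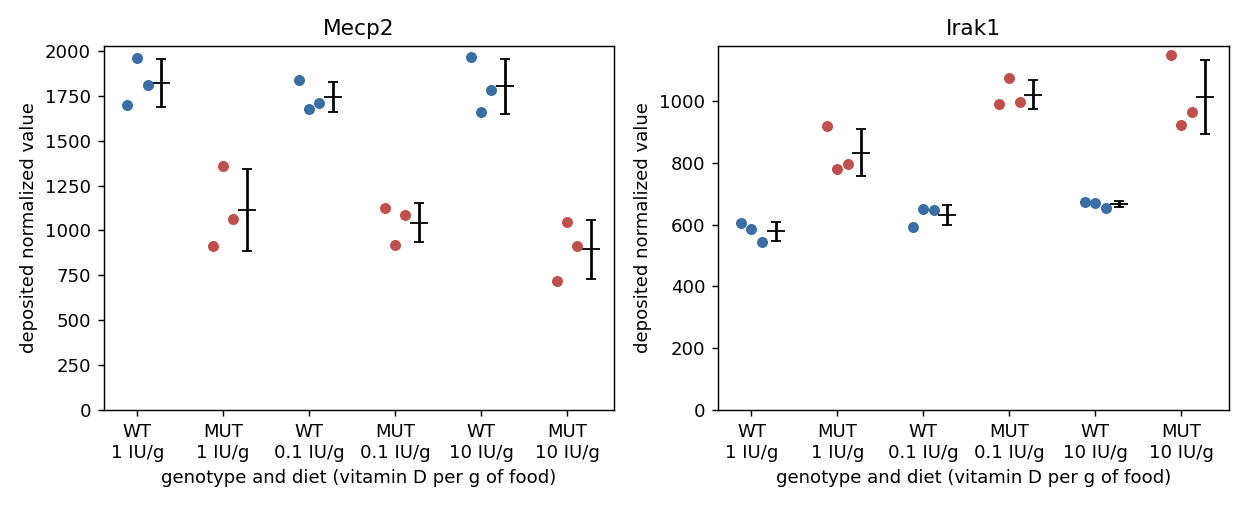
Normalized values of Mecp2 and Irak1 in each library by diet and genotype, with points for libraries and bars for mean ± SD (n = 3). Mecp2 runs from 721 to 1360 in MUT and from 1658 to 1965 in WT, and Irak1 from 781 to 1147 in MUT and from 544 to 673 in WT.

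On the control diet of 1 IU/g, the genotypes differed by modest folds in a small set of genes. Rora, a nuclear receptor that also acts in the circadian clock, was 1.52-fold higher in MUT (2258 ± 131 in WT, 3443 ± 176 in MUT, n = 3; log2 0.61, SE 0.08, adjusted p = 0.0073). Tox, a DNA-bending transcription factor, rose from 710 ± 69.0 to 1038 ± 50.9 (log2 0.55), Trpm3, a cation channel, by 0.47, Plcb4, a phospholipase C, by 0.51, Dgkg, a diacylglycerol kinase, by 0.43, Tshz1, a zinc finger transcription factor, by 0.56, and Irak1 by 0.52. Plk5, a polo-like kinase, fell from 387 ± 31.7 to 230 ± 28.7 (log2 -0.75, SE 0.13, adjusted p = 0.019). Lower genes also held Dio2 (-0.56), which activates thyroid hormone, Lpl (-0.67), which splits lipoprotein triglycerides, Mapk3 (-0.38), the kinase ERK1, Ramp3 (-0.72), Scn3b (-0.43), a sodium channel subunit, Qdpr (-0.27), which recycles tetrahydrobiopterin, and Crh (-0.63), the stress peptide corticotropin-releasing hormone. In all, 61 genes were called, 35 higher and 26 lower in MUT, and 2865 had an unadjusted p under 0.05. The median change over all genes moved by under 0.01 with another scaling.

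Microglia markers were lower in MUT on 1 IU/g. Unannotated (TEC) and sense intronic transcripts each had a median of 0.30 for MUT against WT, against 0 for protein-coding genes. Of 1042 TEC features 5 were called higher and 0 lower, and of 89 sense intronic ones 0 were called. The TEC medians of single libraries ran from -0.642 to -0.445 in WT and from -0.309 to -0.202 in MUT. Sense intronic medians overlapped, at -0.675 to -0.316 in WT and -0.414 to -0.26 in MUT. Fcrls (-0.47) and Cx3cr1 (-0.37), the fractalkine receptor, fell over all genes tested, 11 of 22 members passed when adjusted over the list alone, and the list median was -0.23 (camera adjusted p = 6.4e-09; adjusted p = 0.18 with an estimated correlation). Ribosomal protein genes had a median of -0.13 (camera adjusted p = 9.5e-12; adjusted p = 0.5 with an estimated correlation), with 0 of 79 members called by limma over all genes or over the list alone and 23 at an unadjusted p under 0.05. Interneuron markers had a median of -0.09 (camera adjusted p = 0.0096; adjusted p = 0.14 with an estimated correlation), where Crh fell over all genes and 4 of 29 members passed over the list alone; Sst was at -0.34 and Tac2 at -0.54. Circadian clock genes had a median of 0.10 (camera adjusted p = 0.0059; adjusted p = 0.14 with an estimated correlation), with Rora called over all genes and 3 of 19 over the list alone. Astrocyte markers had a median of -0.08 (camera adjusted p = 0.013; adjusted p = 0.57 with an estimated correlation), with 0 of 20 called over all genes, 3 over the list alone and 7 at an unadjusted p under 0.05. Nuclear genes of oxidative phosphorylation had a median of -0.05 (camera adjusted p = 0.004; adjusted p = 0.66 with an estimated correlation), with 0 of 73 called either way and 12 at an unadjusted p under 0.05. Blood cell markers, which other cells than those of cortex bring, had a median of 0.59 (camera adjusted p = 0.012; adjusted p = 0.66 with an estimated correlation), with 0 of 7 called either way and 1 at an unadjusted p under 0.05. Of 32 genes reported elsewhere to respond to MeCP2 loss, 1 rose (Irak1) and 1 fell (Crh) over all genes, and 8 passed when adjusted over the list alone (list median 0.02, camera adjusted p = 0.68). Without MUT replicate 1, the called microglia, interneuron and clock members lost their calls. Of 19 measured vitamin D genes, 0 passed by limma over all genes or over the list alone.

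The count at 1 IU/g moved when single libraries were left out. The count of 61 became 11 without WT replicate 1, 6 without WT replicate 2, 352 without WT replicate 3, 1 without MUT replicate 1 and 13 without MUT replicate 2, and each of the 24 genes taken by the naming rule kept its sign and lost its call in at least 1 such fit (24 without MUT replicate 1, 23 without WT replicate 2, 21 without WT replicate 1, 15 without MUT replicate 2 and 8 without MUT replicate 3). Without MUT replicate 1, Rora stood at 0.57, Tox at 0.54, Dio2 at -0.54, Plk5 at -0.64 and Crh at -0.49. The count was 956 with 12 residual degrees of freedom, 432 at an adjusted p under 0.10, 31 with array weights and 38 with the trend on 3' base composition removed.

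On the low diet of 0.1 IU/g, a large share of the genes was called between the genotypes. Isca2, which builds mitochondrial iron-sulfur clusters, was 3.65-fold higher in MUT (log2 1.87, SE 0.12, adjusted p = 1.7e-08). Prpf8, the core protein of the spliceosome, rose from 495 ± 55.3 in WT to 1395 ± 39.1 in MUT (n = 3; log2 1.5), Txn1, thioredoxin, by 1.65 and Nudt3, a phosphohydrolase, from 4777 ± 440 to 12614 ± 599 (log2 1.40). Gapdh, a glycolytic enzyme, fell by 0.93 on the log2 scale, Egln2, an oxygen-sensing prolyl hydroxylase, by 0.85, Sh3bgrl3 by 0.84 and Rnf157, a ubiquitin ligase, by 0.81. Of these genes, Isca2, Prpf8, Txn1 and Nudt3 stood within 0.11 of 0 at 1 IU/g, and each had a negative difference at 10 IU/g (-0.85, -0.41, -0.97 and -0.59). In all, 7619 genes were called, 3928 higher and 3691 lower, so 51.6% were higher. With each library centred on its median the median of all genes shifted by -0.135 and 34.7% of calls were higher. Simulations with 3 shared factors removed gave 0 to 8580 calls where nothing differed. The count of 7619 and that of 3253 at 10 IU/g lie inside this range, so the counts alone do not show a genotype effect. Camera called 0 of 31 lists, 7 had an unadjusted p under 0.05, and fry called 10. TEC transcripts had a median of 0.30 (209 higher, 20 lower) and sense intronic ones 0.27. Blood cell markers had the highest list median, 0.76, and were not called (camera adjusted p = 0.16).

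On the high diet of 10 IU/g, many of the genes that differed on 0.1 IU/g differed in the opposite direction. Of the genes called here, 2326 were called in the opposite direction on 0.1 IU/g and 123 in the same direction. Rims3, a protein of the presynaptic active zone, rose 1.49-fold in MUT (log2 0.58, SE 0.06, adjusted p = 5.7e-05), Deptor, an inhibitor of mTOR, by 0.67, Ier5, an immediate early gene, by 0.70, and Nmnat2, which makes NAD in axons, by 0.48. Fbxl16, an F-box protein, fell from 4222 ± 217 in WT to 1718 ± 224 in MUT (n = 3; log2 -1.30, adjusted p = 4.8e-05), and rose by 1.28 at 0.1 IU/g. Cs, citrate synthase, fell by 1.17 on the log2 scale, Nus1, a subunit of dolichol synthesis, by 0.99, and mt-Cytb, the mitochondrial cytochrome b gene, by 0.69. In all, 3253 genes were called, 1158 higher and 2095 lower, so 35.6% were higher. With median scaling the median of all genes shifted by 0.114 and 67% were higher, and with the 3' trend removed 46.7% were.

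Ribosomal protein genes were higher in MUT on 10 IU/g, with 27 of 79 higher and 4 lower over all genes, 41 passing over the list alone and a median of 0.17 (camera adjusted p = 1.1e-08; adjusted p = 0.71 with an estimated correlation). Nuclear oxidative phosphorylation genes had 21 higher and 8 lower of 73, and 38 passed over the list alone. Their median was 0.14 (camera adjusted p = 0.00013; adjusted p = 0.71 with an estimated correlation). TEC transcripts were lower in MUT, with a median of -0.22 (60 lower, 4 higher), and sense intronic ones had -0.21. The TEC medians of single libraries ran from 0.354 to 0.431 in WT and from 0.133 to 0.217 in MUT. Immediate early genes had a median of 0.42 with Ier5 alone called of 29, over all genes and over the list alone (camera adjusted p = 0.0021; adjusted p = 0.71 with an estimated correlation). Striatal markers were lower, with 4 of 19 called over all genes and over the list alone. Their median was -0.65 (camera adjusted p = 0.00073; adjusted p = 0.71 with an estimated correlation), and moved with these groups. Blood cell markers had a median of 0.59 (camera adjusted p = 0.031; adjusted p = 0.71 with an estimated correlation), with 0 of 7 called by limma either way and 2 at an unadjusted p under 0.05. Without WT replicate 1, 6 oxidative phosphorylation genes were higher and 5 lower and 1 striatal marker was lower, and without MUT replicate 2, 14 ribosomal protein genes were higher and 2 lower. The gene count became 1657 without WT replicate 1, 2055 without WT replicate 2 and 2033 without MUT replicate 2 of this diet, and each of these named genes stayed called in every fit without 1 library.

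Averaged over the diets, MUT differed from WT in 2500 genes, 1189 higher and 1311 lower. Rora rose by 0.59 (SE 0.05, adjusted p = 2.7e-06), with 0.61, 0.55 and 0.62 at 1, 0.1 and 10 IU/g, from a mean of 2683 to 3934 ± 153 on 0.1 IU/g and from 2570 ± 87.2 to 3981 ± 508 on 10 IU/g (n = 3). Tox rose by 0.61, Tshz1 by 0.57, Nell1, a secreted growth factor, by 0.53, Trpm3 by 0.45, Nova1, a neuronal splicing factor, by 0.44, and Rims3 by 0.43. Efna5, an axon guidance ligand, rose by 0.60, Maf, a transcription factor of interneurons, by 0.40, and Tenm2, a synaptic adhesion protein, by 0.35. Lower genes were Psd (-0.41), an exchange factor of postsynaptic ARF6, Cyp46a1 (-0.37), which turns brain cholesterol into 24-hydroxycholesterol, Scn3b (-0.45), Slc8a2 (-0.36), a sodium-calcium exchanger, Ddn (-0.37), a dendritic protein, Amz1 (-0.51), Aplp1 (-0.36), a relative of the amyloid precursor, Hrh3 (-0.52), the histamine H3 receptor, and Arhgdig (-0.45). Each of these lower genes differed most at 0.1 IU/g: Cyp46a1 stood at -0.31, -0.81 and 0.00 at 1, 0.1 and 10 IU/g, and Psd at -0.31, -0.80 and -0.11.

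TEC transcripts had a median of 0.15 averaged over diets (51 higher, 4 lower) and sense intronic ones 0.14. Microglia markers were lower on average, 9 of 22 over all genes and 13 over the list alone, with a median of -0.19 (camera adjusted p = 3.3e-06; adjusted p = 0.36 with an estimated correlation). Fcrls fell by 0.40 on the log2 scale and Aif1, the marker IBA1, by 0.38, and their values at 10 IU/g were -0.11 and 0.05. Microglia markers did not move alike on each diet. P2ry12 stood at -0.05, 0.79 and -0.58 at 1, 0.1 and 10 IU/g, and Hexb at -0.14, 0.76 and -0.75. C1qa stood at -0.43, -0.39 and 0.15, and Trem2 at -0.44, -0.28 and -0.01. Astrocyte markers had 6 of 20 lower, and 8 passed over the list alone. Their median was -0.09 (camera adjusted p = 0.0061; adjusted p = 0.37 with an estimated correlation), led by Apoe (-0.28), the lipid carrier. Oligodendrocyte precursor markers had 6 of 16 lower, and 8 passed over the list alone. Their median was -0.12 (camera adjusted p = 0.012; adjusted p = 0.15 with an estimated correlation), with C1ql1 at -0.40 and Tmem100 at -0.32. Clock genes had 4 of 19 higher, and 6 passed over the list alone. Their median was 0.12 (camera adjusted p = 0.00029; adjusted p = 0.085 with an estimated correlation), led by Rora and Bhlhe40 (0.45), a clock repressor. Glucocorticoid responsive genes had 6 of 19 higher, and 7 passed over the list alone. Their median was 0.09 (camera adjusted p = 0.019; adjusted p = 0.37 with an estimated correlation), with Tsc22d3 at 0.41, while Fkbp5 (0.42, 1.41 and -0.35 at 1, 0.1 and 10 IU/g) and Klf15 (0.32, 1.69 and -0.47) changed direction between diets. Immediate early genes had 2 of 29 higher over all genes and over the list alone. Their median was 0.22 (camera adjusted p = 8.3e-05; adjusted p = 0.45 with an estimated correlation), with Ier5 at 0.28. Blood cell markers rose with these groups, 3 of 7 over all genes and 5 over the list alone with a median of 0.63 (camera adjusted p = 9.8e-05; adjusted p = 0.37 with an estimated correlation). Without WT replicate 3 on 0.1 IU/g, the called blood cell markers lost their calls and 2 clock genes and 1 immediate early gene stayed called, while 9 immediate early genes were called without WT replicate 3 on 1 IU/g. Of the 32 reported responders to MeCP2 loss, 9 were higher and 5 lower over all genes and 17 passed over the list alone (median 0.05, camera adjusted p = 0.28). Among them Sdk1, an adhesion protein, rose by 0.63 and Crh fell by 0.39 on the log2 scale.

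**Figure D3:**
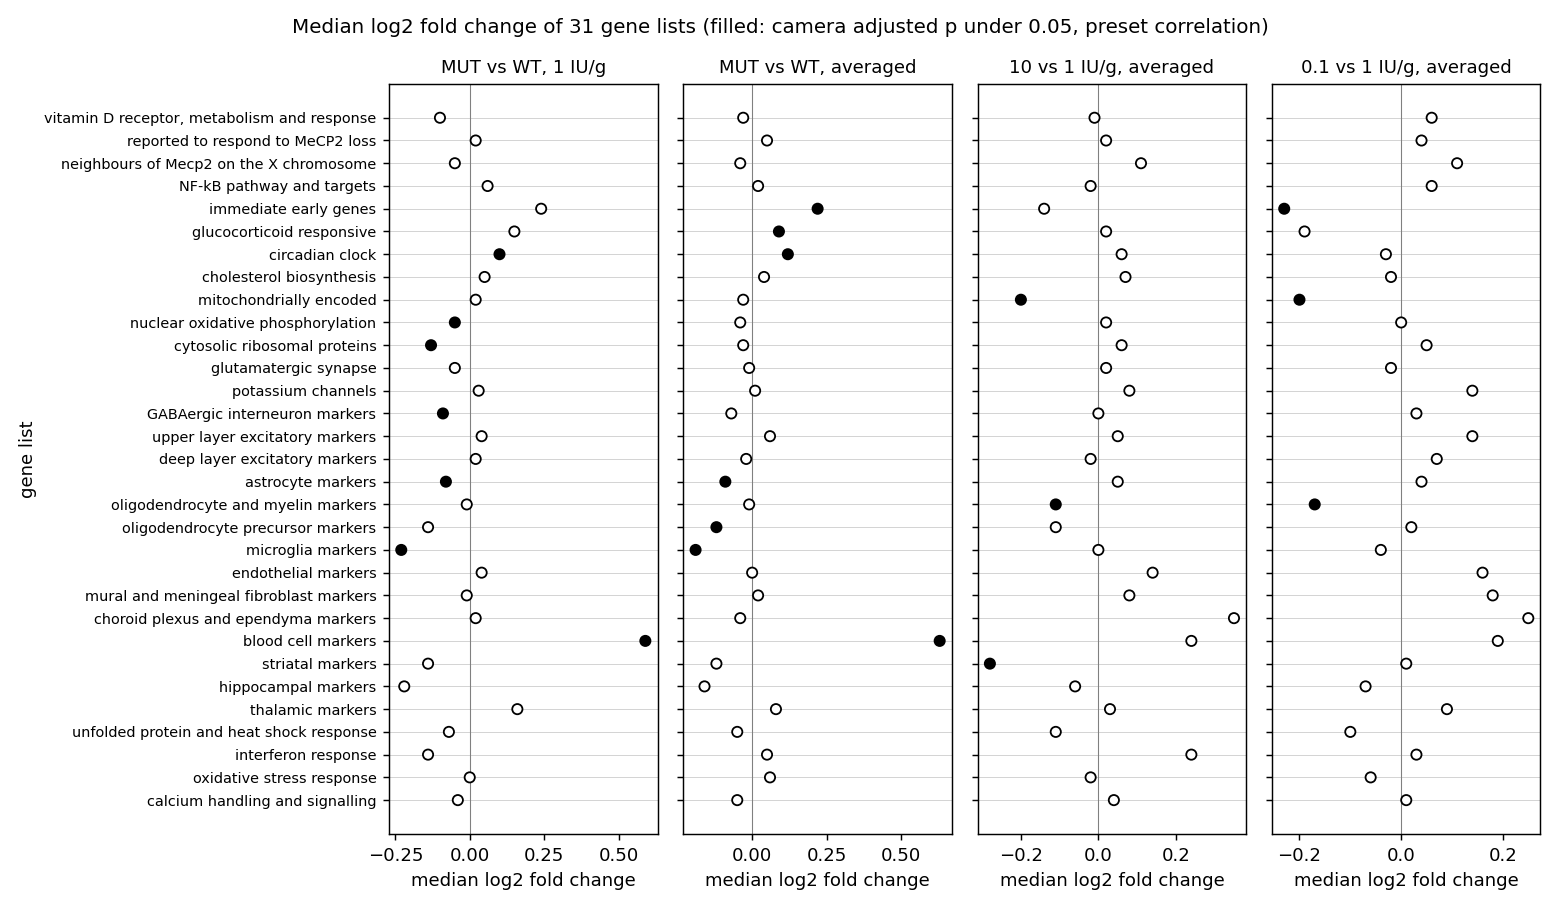
Median log2 fold change of each of the 31 gene lists, with filled points where the camera adjusted p was under 0.05 and open points elsewhere. The contrasts are MUT against WT at 1 IU/g and averaged over diets, and 10 and 0.1 against 1 IU/g averaged over genotypes. Microglia markers lie at -0.23 for MUT against WT at 1 IU/g and at -0.19 averaged over diets, both filled. Each of the diet contrasts has 3 filled points.

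Overlap of the calls differed between pairs of diets. Of the 61 genes called at 1 IU/g, 33 were also called in the same direction and 6 in the opposite direction at 0.1 IU/g, against 13 and 12.8 for independent lists. The counts were 25 and 2 at 10 IU/g, against 5.3 and 5.7. Between 0.1 and 10 IU/g, 123 genes were called in the same direction and 2326 in opposite directions, against 681.6 and 693.9. These comparisons share no library. In each of the 3 diets 18 genes were called, 11 of them in the same direction: Rora, Tox, Irak1, Nell1, Nova1, Tshz1, Trpm3, Plcb4 and 2 predicted or clone genes were higher and Fgf10, a fibroblast growth factor, was lower (-0.65 on average). Genotypes did not overlap in the same direction in all 3 diets for 177 genes, where 227.4 follow from the rates in each diet (19.9%, 62.3% and 40.9% at 1, 0.1 and 10 IU/g) and 4.5 from the 10% that chance gives for 3 against 3. Among the 6511 genes between the quartiles of the loadings on the leading axis, a set chosen after the results were seen, 70 were higher and 67 lower in all 3, where 67.1 in total follow from the rates in that set. Loadings correlated with the genotype effect at 0.87 at 0.1 IU/g and at -0.82 at 10 IU/g. Leaving out large loadings therefore drops genes that moved in opposite directions on these diets. That filter by itself favours the same direction, so no conclusion is drawn from this count. The averaged count became 1653 without WT replicate 2 on 0.1 IU/g and 1083 with the leading axis as a covariate, of which 1010 were among the 2500. It was 4247 with 12 residual degrees of freedom and 6479 without the 10 IU/g diet. Of the 2500, 43.6% had the same direction in all 3 diets. With the spread between the 3 diets as the error, limma called 0 genes, and 348 had an unadjusted p under 0.05.

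**Figure D4:**
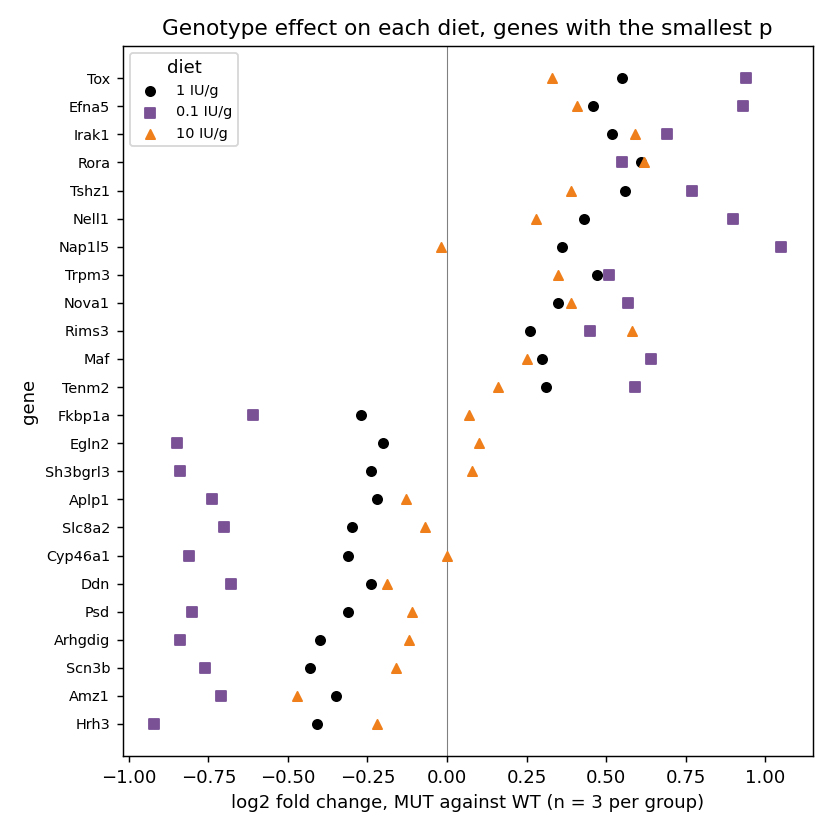
Log2 fold change of MUT against WT at 1, 0.1 and 10 IU/g for the 24 genes with the smallest p averaged over diets, 12 higher and 12 lower. Rora stays between 0.55 and 0.62 on all 3 diets, whereas Cyp46a1 runs from -0.81 at 0.1 IU/g to 0.00 at 10 IU/g.

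The high diet was compared with the control diet in each genotype. In WT, noncoding transcripts had the smallest p among the genes that rose: Snhg11 went from 18341 ± 1190 to 38526 ± 1550 (n = 3; log2 1.07, adjusted p = 5.3e-06), Meg3 from 39338 ± 4280 to 89877 ± 2950 (log2 1.20), and Malat1, an abundant RNA of nuclear speckles, by 1.11. Nktr, a cyclophilin of the nucleus, rose by 0.68. Fbxl3, an F-box protein of the circadian clock, fell by 0.80 on the log2 scale, Slc33a1, the acetyl-CoA transporter of the endoplasmic reticulum, by 0.91, Atrn, attractin, by 0.62, and Rnf7, a ubiquitin ligase subunit, by 0.58. In all, 2069 genes were called, 1645 higher and 424 lower (79.5% higher, against 67.5% with median scaling and 62.2% with the 3' trend removed). TEC transcripts had a median of 1.02 (502 higher, 3 lower) and sense intronic ones 1.09 (47 higher, 0 lower), against 0.02 for protein-coding genes. The unfolded protein and heat shock list had 6 of 25 lower, and 10 passed over the list alone. Their median was -0.21 (camera adjusted p = 4.8e-06; adjusted p = 0.39 with an estimated correlation). Camera called 9 further lists: endothelial markers were higher (median 0.20, 3 of 18 higher, 3 over the list alone), and the others had medians of -0.26 for immediate early genes, -0.15 for microglia, -0.10 for oligodendrocyte, -0.09 for mitochondrially encoded, -0.09 for ribosomal, -0.08 for oxidative phosphorylation, -0.07 for interneuron and -0.07 for oxidative stress genes. Their largest camera adjusted p was 0.043, and none of the 10 stayed called (adjusted p = 0.22 to 0.59 with an estimated correlation). Without WT replicate 2 on 10 IU/g, 2 genes of the unfolded protein list were lower and 1 endothelial marker was higher, and the called interneuron, oligodendrocyte, microglia, oxidative phosphorylation and oxidative stress members lost their calls. Fry called 0 lists here, and 8 had an unadjusted p under 0.05. The gene count became 780 without WT replicate 2 and 1001 without WT replicate 3 on 10 IU/g, and 3490 with 12 residual degrees of freedom.

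In MUT, 6881 genes were called between the high and the control diet, 3680 higher and 3201 lower on the high diet. Snhg11 rose from 19886 ± 864 to 46298 ± 5750 (n = 3; log2 1.21), Rasgrf2, an exchange factor of upper layer neurons, by 0.97, Atp6ap1, a subunit of the vacuolar proton pump, by 0.67, and Kcnj9, a potassium channel, by 0.66. Fbxl16 fell from 7412 ± 152 to 1718 ± 224 (log2 -2.12, SE 0.11, adjusted p = 4.1e-08), Nus1 by 1.53 on the log2 scale, Mrpl27, a mitochondrial ribosomal protein, by 1.51 and Klhl9, an adaptor of a ubiquitin ligase, by 1.41. Ribosomal protein genes had 38 of 79 higher and 7 lower, and 45 passed over the list alone. Their median was 0.20 (camera adjusted p = 0.0014; adjusted p = 0.96 with an estimated correlation). Mitochondrially encoded genes had 8 of 15 lower over all genes and over the list alone. Their median was -0.26 (camera adjusted p = 0.0039; adjusted p = 0.96 with an estimated correlation). Striatal markers moved with them, 5 of 19 lower either way with a median of -0.63 (camera adjusted p = 0.005; adjusted p = 0.96 with an estimated correlation). Without MUT replicate 2 on 10 IU/g, 24 ribosomal protein genes were higher and 4 lower, and 10 striatal markers were lower without MUT replicate 1 and 3 without MUT replicate 3. With median scaling 66% of calls were higher, against 53.5%. TEC transcripts had a median of 0.48 (256 higher, 37 lower) and sense intronic ones 0.58, against 0.06 for protein-coding genes. Of the genes called in WT, 1236 were called in the same direction in MUT and 12 in the opposite one, against 411.3 and 378.8 for independent lists.

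The low diet was also compared with the control diet. In WT it gave the largest count of the 14 contrasts, 8678 genes, 4958 higher and 3720 lower (57.1% higher, against 67.5% with median scaling). Nudt3 fell from 14252 ± 1280 to 4777 ± 440 (n = 3; log2 -1.58, SE 0.09, adjusted p = 2.2e-09), mt-Cytb from 586899 ± 24700 to 251225 ± 22200 (log2 -1.23), Sdhc, a subunit of complex II, by 1.47 on the log2 scale, and Akt1, a kinase of insulin signalling, by 1.17. Rnf6, a ubiquitin ligase, rose by 1.03, Rprd1b, a regulator of RNA polymerase II, by 1.02, Prpf4b, a splicing kinase, by 0.84, and Stox2 by 0.80. Camera called 0 of 31 lists, 4 had an unadjusted p under 0.05, and fry called 10. TEC transcripts had a median of 0.62 (407 higher, 41 lower) and sense intronic ones 0.69, against 0.08 for protein-coding genes. In MUT, 2050 genes were called, 1177 higher and 873 lower (57.4% higher, against 46.8% with median scaling and 39.4% with the 3' trend removed). Snhg11 rose by 0.81, Xist from 3034 ± 337 to 4866 ± 369 (log2 0.69, adjusted p = 9e-05), Arhgap32, a neuronal Rho GTPase activating protein, by 0.44, and mt-Td, a mitochondrial transfer RNA, by 1.58. Arl8a, a GTPase of lysosome transport, fell by 0.82 on the log2 scale, Brd2, a chromatin reader, by 0.74, Hspe1-rs1 by 0.67 and Gapdh by 0.62.

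In MUT on the low diet, TEC transcripts had a median of 0.65 (251 higher, 2 lower) and sense intronic ones 0.73, against 0.02 for protein-coding genes. Mitochondrially encoded genes had 6 of 15 lower, and 8 passed over the list alone. Their median was -0.31 (camera adjusted p = 0.00015; adjusted p = 0.73 with an estimated correlation). Oligodendrocyte and myelin markers had 4 of 24 lower, and 5 passed over the list alone. Their median was -0.22 (camera adjusted p = 0.00023; adjusted p = 0.73 with an estimated correlation). Nuclear oxidative phosphorylation genes had 11 of 73 lower and 2 higher, and 15 passed over the list alone. Their median was -0.06 (camera adjusted p = 0.00015; adjusted p = 0.73 with an estimated correlation). Immediate early genes had 1 of 29 higher and 1 lower, and 2 passed over the list alone. Their median was -0.26 (camera adjusted p = 0.024; adjusted p = 0.73 with an estimated correlation). Without MUT replicate 3 on 0.1 IU/g, 1 mitochondrially encoded gene, 1 oligodendrocyte marker and 4 oxidative phosphorylation genes were lower, and the called immediate early genes lost their calls. WT and MUT shared 1261 calls in the same direction and 127 in the opposite one, against 504.1 and 483.2 for independent lists. The count in MUT became 550 without MUT replicate 3 and 1075 without MUT replicate 2 on 0.1 IU/g, and 999 without MUT replicate 2 and 969 without MUT replicate 3 on 1 IU/g. It was 3727 with 12 residual degrees of freedom, 3243 with only the groups compared and 3213 at an adjusted p under 0.10.

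Many of the same genes differed from the control diet in the same direction on the low and high diets. The genes called for 10 against 1 IU/g in WT and for 0.1 against 1 IU/g in MUT, which share no library, held 753 in common in the same direction and 0 in the opposite one, against 128 and 107.4 for independent lists. For 0.1 against 1 IU/g in WT and 10 against 1 IU/g in MUT, the counts were 5054 and 43, against 1673.5 and 1640.6. Fold changes correlated with the leading-axis loadings at -0.64 and -0.47 for the first pair and at -0.96 and -0.93 for the second. A shared shift of the 1 IU/g groups along that axis would give such sharing, and diet and an unstated batch cannot be told apart as its source. A set of 11 nuclear transcripts, chosen after their values were seen, had a median change of 0.63 at 10 against 1 IU/g and of 0.667 at 0.1 against 1 IU/g.

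Averaged over genotypes, 10 against 1 IU/g called 7461 genes, 4514 higher and 2947 lower (60.5% higher, against 49.7% with the 3' trend removed). Snhg11 rose by 1.14 (SE 0.06, adjusted p = 2.2e-08), Meg3 by 1.09, Tra2a, a splicing regulator, by 0.65, Nktr by 0.63 and Xist by 0.52. Slc33a1 fell by 1.45 on the log2 scale, Fbxl16 by 1.37, Fbxl3 by 1.11 and Atrn by 0.99. TEC transcripts had a median of 0.78 (636 higher, 27 lower) and sense intronic ones 0.86 (65 higher, 0 lower), against 0.05 for protein-coding genes. Oligodendrocyte and myelin markers had 10 of 24 lower over all genes and over the list alone. Their median was -0.11 (camera adjusted p = 0.013; adjusted p = 0.81 with an estimated correlation). Plp1, the main protein of myelin, went from 29913 ± 2360 to 18086 ± 1580 in WT and from 30980 ± 1640 to 9125 ± 2060 in MUT (n = 3; log2 -1.26). Mitochondrially encoded genes had 9 of 15 lower either way. Their median was -0.20 (camera adjusted p = 0.0016; adjusted p = 0.81 with an estimated correlation), with mt-Cytb at -0.50 and mt-Co2 at -0.56. Striatal markers moved with these groups, 5 of 19 lower either way with a median of -0.28 (camera adjusted p = 0.012; adjusted p = 0.82 with an estimated correlation). Scn4b, a sodium channel subunit of striatal neurons, went from 990 ± 3.61 to 657 ± 140 in WT and from 1155 ± 398 to 182 ± 96.1 in MUT. Bdnf, brain-derived neurotrophic factor, fell from 1116 ± 198 to 809 ± 41.8 in WT and from 1238 ± 149 to 862 ± 63.8 in MUT (log2 -0.48, adjusted p = 8.8e-05). With the leading axis as a covariate 2268 genes were called, and mt-Cytb stood at 0.13, mt-Co2 at 0.09 and Scn4b at 0.20. With the spread between the genotypes as the error 28 genes were called.

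Averaged over genotypes, 0.1 against 1 IU/g called 8281 genes, 4768 higher and 3513 lower. Snhg11 rose by 0.92, Xist by 0.67, Stox2 by 0.63, Nktr by 0.62 and Fbxo41, a neuronal F-box protein, by 0.58. Cdkn2d, a cell cycle inhibitor, fell by 0.91 on the log2 scale, mt-Cytb by 0.82 (SE 0.05, adjusted p = 3e-08), Arl8a by 0.79 and Tagln3, a neuronal cytoskeletal protein, by 0.70. TEC transcripts had a median of 0.66 (582 higher, 33 lower) and sense intronic ones 0.66 (58 higher, 0 lower), against 0.04 for protein-coding genes. Oligodendrocyte and myelin markers had 11 of 24 lower over all genes and over the list alone. Their median was -0.17 (camera adjusted p = 0.0016; adjusted p = 0.99 with an estimated correlation), with Plp1 at -1.20, Mbp, myelin basic protein, at -0.72 and Mog at -0.54. Mitochondrially encoded genes had 9 of 15 lower and 1 higher, and 10 passed over the list alone. Their median was -0.20 (camera adjusted p = 0.011; adjusted p = 0.99 with an estimated correlation). Immediate early genes had 7 of 29 lower and 1 higher, and 7 passed over the list alone. Their median was -0.23 (camera adjusted p = 0.021; adjusted p = 0.99 with an estimated correlation), with Nr4a1 at -1.71, Dusp6 at -1.04, Ptgs2 at -0.90 and Klf4 at 0.67. Without WT replicate 1 on 1 IU/g 14 were lower, and without MUT replicate 2 on 1 IU/g 4. With the leading axis as a covariate 2791 genes were called, and Mbp stood at 0.11, mt-Co2 at 0.14 and Dusp6 at 0.02. With the spread between the genotypes as the error limma called 0 genes, and 2693 had an unadjusted p under 0.05.

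The ends of the dose range were compared within each genotype. In WT, 10 against 0.1 IU/g called 5760 genes, 3342 higher and 2418 lower. Nudt3 rose by 1.47 (SE 0.09, adjusted p = 3e-08), Brox, an endosomal protein, by 1.39, Sdhc by 1.26 and Tspoap1, a presynaptic protein, by 1.14. Ppp2r3c fell by 0.68 on the log2 scale, Rprd1b by 0.63, Sub1, a transcriptional coactivator, by 0.56 and Smarca2, a chromatin remodeller, by 0.52. TEC transcripts had a median of 0.35 (186 higher, 7 lower), against -0.02 for protein-coding genes. Ribosomal protein genes had 35 of 79 lower and 12 higher, and 54 passed over the list alone. Their median was -0.18 (camera adjusted p = 0.0041; adjusted p = 0.99 with an estimated correlation). Without WT replicate 3 on 0.1 IU/g, 16 were lower and 8 higher. Fry called 0 lists in WT, and 7 had an unadjusted p under 0.05. In MUT, 5389 genes were called, 2529 higher and 2860 lower. Gapdh rose by 0.69 (SE 0.07, adjusted p = 4.1e-06), Rnf157 by 0.68, Kctd2 by 0.68 and Dctn1, a subunit of dynactin, by 0.65. Fbxl16 fell by 1.63 on the log2 scale, Nus1 by 1.26, Ubl3 by 1.02 and Cdk17 by 0.84. TEC transcripts had a median of -0.17 in MUT (11 higher, 84 lower), against 0 for protein-coding genes. Ribosomal protein genes had 27 of 79 higher and 5 lower in MUT, and 35 passed over the list alone. Their median was 0.14 (camera adjusted p = 5.6e-05; adjusted p = 0.95 with an estimated correlation). Nuclear oxidative phosphorylation genes had 41 of 73 higher and 8 lower, and 53 passed over the list alone. Their median was 0.20 (camera adjusted p = 5.6e-05; adjusted p = 0.95 with an estimated correlation). The X-linked neighbours of Mecp2 had 6 of 29 higher and 2 lower, and 8 passed over the list alone. Their median was 0.20 (camera adjusted p = 0.026; adjusted p = 0.73 with an estimated correlation). Striatal markers moved with these groups in MUT, 4 of 19 lower either way with a median of -0.76 (camera adjusted p = 0.00054; adjusted p = 0.95 with an estimated correlation). Without MUT replicate 3 on 0.1 IU/g, 15 ribosomal protein genes were higher and 4 lower in MUT, and 11 striatal markers were lower without MUT replicate 1 on 10 IU/g and 2 without MUT replicate 2. With median scaling 35% of the calls were higher in WT, against 58%, with a shift of the median of all genes of -0.135, and 66.8% in MUT, against 46.9%, with a shift of 0.114. The count in WT became 3829 without WT replicate 2 and 3698 without WT replicate 3 on 0.1 IU/g, and 8890 with only the groups compared.

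The difference of the genotype effect between diets was tested directly. Between 10 and 1 IU/g it called 1893 genes, 643 with a higher and 1250 with a lower genotype effect at 10 IU/g (34% higher, against 67.2% with median scaling, which shifted the median of all genes by 0.123). Fbxl16 went from a genotype effect of 0.20 at 1 IU/g to -1.30 at 10 IU/g (difference -1.50, SE 0.15, adjusted p = 0.0011), Inpp5e, a phosphatase of the primary cilium, differed by -1.73, Cnep1r1 by -1.41 and Mrpl27 by -1.02. Jdp2, an AP-1 repressor, differed by 0.88, Smg7, a factor of nonsense-mediated decay, by 0.78, Atp6ap1 by 0.60 and Dnajb1, a heat shock cochaperone, by 0.58. TEC transcripts had a median of -0.53 (1 higher, 72 lower) and sense intronic ones -0.56, against -0.03 for protein-coding genes. Ribosomal protein genes had 30 of 79 higher and none lower, and 49 passed over the list alone. Their median was 0.28 (camera adjusted p = 1.3e-17; adjusted p = 0.41 with an estimated correlation). Nuclear oxidative phosphorylation genes had 15 of 73 higher and 6 lower, and 43 passed over the list alone. Their median was 0.19 (camera adjusted p = 1.1e-06; adjusted p = 0.74 with an estimated correlation), with Sdhc at -0.73 and Uqcrfs1 at -0.92 among the lower ones. Microglia markers had 3 of 22 higher and 1 lower, and 5 passed over the list alone. Their median was 0.15, with Csf1r at 0.62, Cx3cr1 at 0.51 and Hexb at -0.61, and the unfolded protein list had 4 of 25 higher, and 9 passed over the list alone. Their median was 0.19 (both camera adjusted p = 0.037; adjusted p = 0.82 with an estimated correlation). The neighbours of Mecp2 had 3 of 29 higher over all genes and over the list alone. Their median was 0.14 (camera adjusted p = 0.037; adjusted p = 0.41 with an estimated correlation), led by Atp6ap1. Without WT replicate 2 on 10 IU/g, 1 neighbour of Mecp2, 1 gene of the unfolded protein list and 18 ribosomal protein genes were higher. Oxidative phosphorylation genes had 4 higher and 5 lower without WT replicate 1 on 10 IU/g, and 28 higher and 5 lower without MUT replicate 1. Fry called 0 lists for this difference, and 5 had an unadjusted p under 0.05. The count became 1199 without MUT replicate 2 on 1 IU/g, 984, 1175 and 1254 without WT replicates 1, 2 and 3 on 10 IU/g and 979 without MUT replicate 2 on 10 IU/g. It was 3693 with 12 residual degrees of freedom, 2914 with only the groups compared, 3149 at an adjusted p under 0.10 and 1198 with the 3' trend removed.

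Between 0.1 and 1 IU/g the difference called 4233 genes, 2366 higher and 1867 lower (55.9% higher, against 34.9% with median scaling, which shifted the median of all genes by -0.126). Bcar1, a scaffold of focal adhesions, differed by 2.0 (SE 0.16, adjusted p = 1.5e-06), Prpf8 by 1.61, Nudt3 by 1.5 and Pip4k2c, a lipid kinase, by 1.35. Gapdh differed by -0.89, Ndufb7, a subunit of complex I, by -0.77, Stmn3, a microtubule regulator, by -0.74 and Rnf157 by -0.74. Camera called 0 of 31 lists, 1 had an unadjusted p under 0.05, and fry called 1.

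Genes called for MUT against WT at 1 IU/g were followed into the diet contrasts of MUT, to see whether diet moved them back. Of the 61 genes, 34 (55.7%) changed in the opposite direction for 10 against 1 IU/g, 22 of them called in both and 12 called in both in the same direction, and 30 (49.2%) for 0.1 against 1 IU/g, with 4 and 10 called in both. The MUT libraries on 1 IU/g enter both contrasts with opposite sign, so opposite directions arise with no diet effect: simulations of that kind gave 79% (75.7 to 83.8) and 79.5% (74.6 to 82), and simulations with the diet effects of WT dealt to random genes gave 62.9% (58.4 to 69.5) and 58% (52.5 to 63.4). Both used genotype effects shrunk by 0.76, after a first version without shrinkage had been seen, and called 366 and 362 genes on average, more than the 61 observed. For 10 against 1 IU/g, genes called in both in opposite directions averaged 0.08 with no diet effect and 86.1 with the dealt diet effects, against 22 observed. Those called in both in the same direction averaged 0 and 51.4, against 12 observed. The observed shares of opposite directions were below those of both kinds of simulation. The share for 10 against 1 IU/g was 38.5% without MUT replicate 2 and 100% without MUT replicate 1 on 1 IU/g, where a single gene was called.

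Genes chosen on libraries outside the tested contrast avoid that overlap. They were followed in the difference of the genotype effect between diets, which also holds the diet change in WT. The 6720 genes chosen at 0.1 IU/g and oriented by their sign there had a mean genotype effect of 0.0731 at 1 IU/g and -0.271 at 10 IU/g, a difference of -0.344. The 3364 genes chosen at 10 IU/g had means of -0.00685 at 1 IU/g and -0.6 at 0.1 IU/g, a difference of -0.593. As both sets had means near 0 at 1 IU/g, these differences do not show whether diet moved a genotype effect back. A further set of 542 genes was called on average over all libraries, with the leading axis as a covariate and a loading in the middle of the range. Its mean oriented effect was 0.251, 0.391 and 0.211 at 1, 0.1 and 10 IU/g, with differences of -0.0398 between 10 and 1 IU/g and 0.14 between 0.1 and 1 IU/g. Across genes, the loadings correlated with these tested differences at -0.74 and 0.84. Leaving out genes with large loadings therefore favours small differences in this set. The 2500 genes called on average without the axis gave -0.22 and 0.416.

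Long genes were compared with other genes because MeCP2 loss has been studied for an effect on them. The 2289 genes longer than 100 kb had a median log2 change of 0.045 for MUT against WT averaged over diets and the others -0.003, a difference of 0.048, and Spearman's rho of fold change with length was 0.087 across 17653 genes. Among 14020 protein-coding genes the difference was 0.054 and rho 0.182. Over all 17653 genes the difference was 0.072 at 1 IU/g, 0.07 at 0.1 IU/g and 0.018 at 10 IU/g. It was 0.018 on average with the 3' trend removed (rho 0.002). Among protein-coding genes it was 0.089 at 1 IU/g (rho 0.221), 0.089 at 0.1 IU/g (rho 0.126) and 0.007 at 10 IU/g (rho -0.016).

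Vitamin D genes moved little as a group. Vdr, the vitamin D receptor, had values of 3 to 16 in single libraries, near the bottom of the table, and log2 changes of -0.28 (SE 0.29) for MUT against WT averaged over diets, 0.24 (SE 0.36) for 10 against 1 IU/g and 0.52 (SE 0.36) for 0.1 against 1 IU/g, none past the threshold. Of the 19 measured members, 1 was higher and 2 lower in MUT averaged over diets, 3 over the list alone (median -0.03, camera adjusted p = 0.56), with Calb1, a calcium buffer, at -0.28 and Slc8a1, a sodium-calcium exchanger, at 0.19. For 10 against 1 IU/g averaged over genotypes, 2 were higher and 4 lower, 6 over the list alone (median -0.01, camera adjusted p = 0.57), with Ngf, nerve growth factor, at -1.09 and Rxrb, a partner of the receptor, at 0.26. For 0.1 against 1 IU/g, 2 were higher and 4 lower, 4 over the list alone (median 0.06, camera adjusted p = 0.99), with Ngf at -1.32 and Pdia3, a protein disulfide isomerase, at 0.44. With the leading axis as a covariate Ngf stood at 0.53 and 0.42. Rxra, the main partner of the receptor in most tissues, lay within 0.01 of 0 in the 3 averaged contrasts.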

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

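The tests of explanations, the simulated libraries and the counts of splits in this part were chosen after the results were seen, and the tests of the difference of the genotype effect between diets were planned.

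The genotype effect differed between diets for many genes. Between 10 and 1 IU/g, 1893 genes passed, among them Atp6ap1 (0.60), Dnajb1 (0.58), Smg7 (0.78), Jdp2 (0.88), Fbxl16 (-1.50), Cnep1r1 (-1.41), Inpp5e (-1.73) and Mrpl27 (-1.02). Between 0.1 and 1 IU/g, 4233 genes passed, among them Bcar1 (2.0), Prpf8 (1.61), Nudt3 (1.5), Pip4k2c (1.35), Gapdh (-0.89), Rnf157 (-0.74), Ndufb7 (-0.77) and Stmn3 (-0.74).

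The leading axis took 58.3% of the variance. Its loadings followed GC content over the last 100 bases of transcripts more closely than over bases further in (rho -0.406 against -0.169, a difference of 0.237 in size), so it may reflect base composition at 3' ends, as a step of library making could give. The mean share of ribosomal RNA in the values also differed between groups. It was highest at the low end of the axis, at 0.692% in WT on 0.1 IU/g and 0.456% in MUT on 10 IU/g. The share was 0.333% in MUT on 0.1 IU/g, 0.303% in WT on 10 IU/g, and 0.176% in WT and 0.288% in MUT on 1 IU/g. Whether the axis reflects this share was not tested. Vitamin D dose alone would give WT and MUT the same score on a diet, but they differed by 0.472 on 0.1 IU/g, above the bound of 0.221. That bound rests on SDs within groups left after factors estimated from residuals were removed. It may be too small, so dose alone is not excluded. Cell type makeup stays open: 218 markers of all types had a median absolute loading of 0.441, inside the 0.383 to 0.609 of random gene sets, while list medians ran from -0.447 for choroid plexus to 0.437 for striatal markers. The labels give no batch, so batch and group cannot be told apart here; splits of the libraries are given below.

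Of 11 nuclear transcripts picked after their values were seen, 9 were called higher at both 0.1 and 10 against 1 IU/g averaged over genotypes, while Snhg14 stood at -0.33 in MUT at 10 IU/g and in WT at 0.1 IU/g. Unannotated and intronic classes exceeded protein-coding genes by at least 0.62 on the log2 scale in the diet contrasts averaged over genotypes, so a larger share of unspliced or intergenic RNA is possible. A response graded with dose needs opposite signs on the 2 diets. Both whole classes were higher on both diets within each genotype, by at least 0.44 between group means, and the unannotated class passed its bound of 0.30 (3 times the largest SD within a group) each time. The intronic class missed its bound of 0.62 in MUT on 10 IU/g (0.60). Both diets were compared with the same libraries on 1 IU/g. A shift of those groups from an unstated batch would give the same sign on both diets whatever the response to dose. A graded response is therefore not settled by either class.

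Long genes were higher in MUT by 0.048. With the trend on 3' base composition removed the difference was 0.018, so that composition may carry part of it, while with the leading axis as a covariate it stayed at 0.046. Of 100 splits, 2 gave a difference as large, and the highest other was 0.049.

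For 3 against 3 libraries only 10 splits exist, so a share never goes under 0.1. The table had factors estimated from residuals removed before these splits were made, which may favour the labelled groups. Splits without any effect were simulated only for the contrast averaged over diets. The gene counts below therefore cannot tell a group difference from a result of that removal. The labelled split gave more called genes than any other in each contrast (1 of 10): 61 against 1 for MUT against WT at 1 IU/g, 7619 against 0 at 0.1 and 3253 against 0 at 10 IU/g. For 10 against 1 IU/g the counts were 2069 against 0 in WT and 6881 against 2 in MUT. For 0.1 against 1 IU/g they were 8678 against 0 and 2050 against 0, and for 10 against 0.1 IU/g 5760 against 0 and 5389 against 4.

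For called lists, other splits often gave as many. MUT against WT at 1 IU/g gave 7 lists, as many as in 6 of 10 splits (highest other 11), and at 10 IU/g 5 lists, 6 of 10 (11). For 10 against 1 IU/g, WT gave 10 lists, 1 of 10 (9), and MUT 3 lists, 7 of 10 (11). MUT at 0.1 against 1 IU/g gave 4 lists, 8 of 10 (13). For 10 against 0.1 IU/g, WT gave 1 list, 9 of 10 (4), and MUT 4 lists, 8 of 10 (8).

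Of 100 splits of averaged contrasts, 2 gave as many genes as the 2500 for MUT against WT (highest other 2761) and 20 as many lists as the 7 (14). For the difference between 10 and 1 IU/g, 1 gave as many as 1893 genes (1074) and 67 as many as 5 lists (14). For that between 0.1 and 1 IU/g, 3 gave as many as 4233 genes (4806). For 10 against 1 IU/g, 1 gave as many as 7461 genes (4333) and 86 as many as 3 lists (15). For 0.1 against 1 IU/g, 1 gave as many as 8281 genes (5410) and 73 as many as 3 lists (13). In 20 simulations of MUT against WT averaged over diets without any effect, with 6000 genes, 20 splits and 3 factors removed, the labelled split called the most genes in 2, where 1 is expected by chance. Mean calls in them were 14.8 for the labelled split and 234 for the highest other split.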

How the results depend on the processing

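Pseudocounts of 0.5 and 10, median scaling and the stricter filter moved no count of called genes by over 1.5 times; the stricter filter gave 58 at 1 IU/g and 2568 averaged over diets. The replicate block gave 84 and 2605 and changed none of 17 results, while of 266 further ones 2 became weaker and 2 stronger; the replicate block numbers do not pair the libraries (correlations -0.79 to 0.46). Except where the model itself shows it, the cause was not tested.

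With 12 residual degrees of freedom, counts were 956 for MUT against WT at 1 IU/g, 4247 averaged over diets, 3490 for 10 against 1 IU/g in WT, 3727 for 0.1 against 1 IU/g in MUT and 3693 for the difference between 10 and 1 IU/g. Array weights gave 31 at 1 IU/g. Removing the 3' trend gave 38 at 1 IU/g and 1198 for that difference. An adjusted p under 0.10 gave 432, 3213 for 0.1 against 1 IU/g in MUT and 3149 for that difference. Only the groups compared gave 3243, 2914 for that difference and 8890 for 10 against 0.1 IU/g in WT. The leading axis as a covariate gave 1083 for the averaged genotype effect and 2268 and 2791 for 10 and 0.1 against 1 IU/g. The spread between diets or genotypes as the error gave 0, 28 and 0 (348, 3797 and 2693 at an unadjusted p under 0.05). Without the 10 IU/g diet the averaged count was 6479. With an estimated correlation 0 of 52 list calls stayed. Over all tests of the 31 lists in the 14 contrasts, called or not, 17 had an unadjusted p under 0.05 with that correlation. The 542 genes called on average with the axis as a covariate that lay between the quartiles of its loadings gave a difference of -0.0398 between 10 and 1 IU/g. The 6720 genes chosen at 0.1 IU/g gave -0.344. The filter on loadings by itself favours a small difference.

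Leaving out 1 library gave 1 to 352 genes for MUT against WT at 1 IU/g, 1657 to 2774 at 10 IU/g, 1653 to 2616 averaged, 780 to 1731 for 10 against 1 IU/g in WT, 550 to 1750 for 0.1 against 1 IU/g in MUT, 3698 to 5007 for 10 against 0.1 IU/g in WT, 979 to 2153 for the difference between 10 and 1 IU/g, and 38.5% to 100% for the reversal.

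Some values changed sign, among them called changes far from 0 when the axis was a covariate (Ngf from -1.09 and -1.32, Dusp6 from -1.04). Rxra for the genotype was 0.01 without the 3' trend, 0.03 with the axis, 0.11 without the 0.1 IU/g diet and 0.01 to 0.02 without 1 library; Vdr was -0.42 to 0.00 without 1 library, and Klf15 -0.08 without that diet. For 10 against 1 IU/g, Rxra was 0.02 with median scaling and 0.00 to 0.03 without 1 library, and Nfkbia 0.02 without the 3' trend, -0.18 to 0.04 without 1 library and 0.30 with the axis. For 0.1 against 1 IU/g, Rxra was -0.08 without the 3' trend, -0.16 with the axis and -0.03 to -0.01 without 1 library. With the axis, 10 against 1 IU/g gave mt-Cytb 0.13, mt-Co2 0.09, Olig2 0.10, Myrf 0.26, Scn4b 0.20, Gpr6 0.29, Adcy5 0.45, Penk 0.10, Id3 0.59, Fkbp5 0.25 and Ngf 0.53, and 0.1 against 1 IU/g gave Dusp6 0.02, mt-Co2 0.14, Mbp 0.11, Id3 0.36 and Ngf 0.42.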

Other observations

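The list tests and the genes chosen with the leading axis as a covariate were tests chosen after the results were seen. The choice of genes at 0.1 IU/g was planned.

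With the leading axis as a covariate, the 7 lists called for MUT against WT averaged over diets kept their directions. Clock genes had a median of 0.10 (camera adjusted p = 5.3e-05; adjusted p = 0.03 with an estimated correlation) and microglia markers -0.18 (camera adjusted p = 2.1e-07; adjusted p = 0.21 with an estimated correlation). Immediate early genes had a median of 0.20 (camera adjusted p = 2.1e-06; adjusted p = 0.34 with an estimated correlation) and blood cell markers 0.65 (camera adjusted p = 4.7e-06; adjusted p = 0.28 with an estimated correlation). Oligodendrocyte precursor markers had a median of -0.16 (camera adjusted p = 0.0024; adjusted p = 0.053 with an estimated correlation) and glucocorticoid responsive genes 0.12 (camera adjusted p = 0.0044; adjusted p = 0.22 with an estimated correlation). Astrocyte markers had a median of -0.06 (camera adjusted p = 0.0044; adjusted p = 0.34 with an estimated correlation), and striatal markers were called as well at -0.20 (camera adjusted p = 0.0096; adjusted p = 0.76 with an estimated correlation).

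Among the genes called in each diet, Rora stood at 0.61, 0.55 and 0.62 at 1, 0.1 and 10 IU/g, Irak1 at 0.52, 0.69 and 0.59, and Tox at 0.55, 0.94 and 0.33. Klk6, a serine protease of oligodendrocytes that was not called in each diet, had -0.73, -0.74 and -0.66. Whether the lower median of the microglia markers reflects fewer or altered microglia was not tested, and cell counts would be needed.

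Whether diet moved genotype effects back could not be settled. The difference between 10 and 1 IU/g was -0.344 for 6720 genes chosen at 0.1 IU/g and -0.22 for the 2500 called on average. It was -0.0398 for 542 genes called with the axis as a covariate that also lay between the quartiles of its loadings. That filter by itself favours a small difference, since the loadings correlated with it at -0.74 across genes. The 6720 genes had a mean genotype effect of 0.0731 at 1 IU/g. These sets differ in how they were chosen as well as in the axis, so their comparison does not isolate it. Raw counts with columns tied to samples, a record of batches and a further set of animals would test this.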
